A study of Bos taurus with 9 samples.

How the data were processed

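Gene expression was measured in longissimus dorsi muscle, abdominal adipose tissue and subcutaneous adipose tissue of Yan yellow cattle bulls aged 24 months, with 3 arrays per tissue. Per the labels, total RNA was extracted with a kit for lipid-rich tissue, named for the adipose samples, and biotin-labelled cRNA was prepared by the manufacturer's protocol for a 1-colour Affymetrix bovine array. The labels count 9 bulls and do not say which samples share an animal, so p-values measure the spread between these samples. The labels name RMA as the authors' processing, and its version and settings are not given in the sources used here.

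The deposited table holds 1 intensity per probe set and array, on a linear scale and with near-equal distributions between arrays, from 3.06 to 17450.5. The plan assumed log2 values. The highest values are far beyond the log2 scale that RMA writes, so the log2 of each deposited intensity was taken before any step. No further normalization and no filter on dim probe sets was applied. No pair of arrays held identical values. The table held 24128 probe sets. The 112 Affymetrix control probe sets were left out, and 24016 were tested.

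Probe set names came from the array annotation paired with the reference gene table: 13265 probe sets were named through the gene identifier and 27 kept the annotation's symbol, 13292 in all with 1 symbol, which stand for 9155 genes. Another 86 carried several symbols and 10638 none, and those were tested and counted but not named. No genome coordinates were used. Where a gene had more than 1 probe set, as 2913 did, the probe set with the highest mean over the 9 arrays stood for it.

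A means model of the 3 tissues was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 residual degrees of freedom and 3.752 prior degrees of freedom. The contrasts were adipose tissue (mean of both depots) minus muscle, abdominal minus muscle, subcutaneous minus muscle, and abdominal minus subcutaneous. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the 24016 probe sets, with a threshold of 0.05. An SE is the moderated standard error of a difference. Both depot comparisons with muscle share the muscle arrays, so no overlap between them was computed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

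The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the exceptions named below. There were 34 gene lists with 809 genes, for muscle contraction, energy metabolism, fat metabolism, matrix, signalling, immunity, protein turnover and markers of other cell types; 599 of these genes were measured. Each list with at least 5 measured genes was tested with camera (limma) on 1 probe set per gene, with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 68 tests of both main contrasts. Camera compares a list with the other genes. The test was repeated with a correlation estimated from the data and with fry. Fry tests whether the genes of a list move, on balance, in the same direction and makes no comparison with other genes. Members were also counted at an adjusted p under 0.05 adjusted over the list alone.

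The rule for naming genes took, for adipose tissue against muscle and for the depots, the 8 genes with the largest positive and the 8 with the largest negative passing difference whose arrays did not overlap, leaving out provisional symbols. It also took up to 4 passing members per list with the largest difference, or the member with the smallest p where none passed, and 17 genes fixed in advance. PLIN1, HOXC10, TBX15 and WT1 of the fixed genes had no probe set with 1 symbol. Members named because they moved against the rest of their list, a probe set that differed from its gene's brightest, and genes outside these rules were chosen after their values were seen.

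Alternatives covered the prior variance, filters on dim probe sets, scaling between arrays, array weights, the leading number of the sample title as a block, the arrays in the fit, ambiguous probe sets, the threshold, and leaving out each array in turn. A count with 1 probe set per gene was added after seeing the data. For each comparison, other splits of the arrays into groups of the same sizes were refitted. The procedure was tested on simulated data with the spread of these arrays, 200 changed probe sets of 24016 and 10 simulations. For adipose tissue against muscle it called 19.0%, 71.8%, 94.0% and 99.8% of simulated log2 differences of 0.5, 1, 2 and 4, with 4.5% of calls false. Between the depots it called 8.4%, 62.2%, 94.0% and 99.6%, with 4.96% of calls false. A simulated shift of 0.5 in the 16 endothelial genes among 9155 genes was called in 100% of 20 simulations with the preset and 95.0% with an estimated correlation. Other lists were called in 0.3% and 0% of those tests. The simulated noise was independent between genes, so these rates do not test the preset on lists whose genes vary together. The 200 changed probe sets are also far fewer than passed between adipose tissue and muscle.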

Results

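Messenger RNA was profiled on 9 arrays from bulls of the Yan yellow cattle breed aged 24 months. The tissues were the longissimus dorsi muscle, which is the skeletal muscle along the back, abdominal adipose tissue and subcutaneous adipose tissue, with 3 arrays each. The number of arrays limits the precision. Each value is the log2 of a deposited probe set intensity. The 9 arrays had similar distributions, with a median between 5.75 and 5.79 in muscle, 5.89 on each of the abdominal arrays and between 5.87 and 5.92 in subcutaneous fat. The mean array median was 0.12 higher in adipose tissue than in muscle, and the difference between abdominal and subcutaneous fat was -0.01. A log2 value over 6 was reached by 46.1% to 49.0% of the probe sets of an array. A group mean under 6 is taken here as near background, and the size of a difference from such a group is not exact. The first principal component held 82.8% of the variance and separated muscle from fat. The second held 5.4% and separated the fat depots. The 3'/5' intensity ratio of the glyceraldehyde-3-phosphate dehydrogenase control probe sets, a sign of RNA integrity, moved with tissue. It was 1.01, 0.94 and 0.94 on the muscle arrays, 1.42, 1.62 and 1.26 on the abdominal arrays and 1.74, 1.36 and 1.21 on the subcutaneous arrays. The ratio of the actin control probe sets was 0.963 to 1.036 in muscle, 2.235 to 5.687 in abdominal fat and 3.856 to 8.167 in subcutaneous fat, and their level moved as well, from at least 11244 in muscle to at most 1469.8 in fat. The elongation factor control gave 0.278 to 0.354 in muscle and 0.473 to 0.650 in fat.

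**Figure D1:**
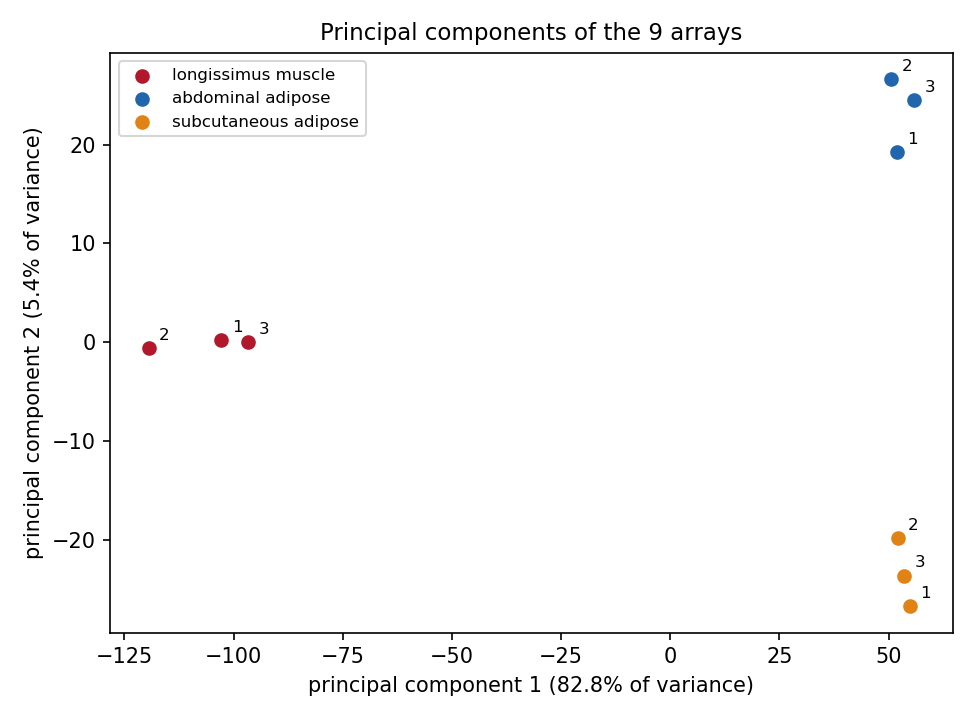
Scores of the 9 arrays on the first principal components of the log2 values, with the percent of variance on each axis and the replicate number beside each point. The muscle arrays lie between -119.42 and -96.65 on the first component. On the second the abdominal arrays lie between 19.23 and 26.59 and the subcutaneous arrays between -26.66 and -19.77.

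The first comparison asked how adipose tissue, as the mean of both depots, differed from muscle. Skeletal muscle genes were far lower in adipose tissue. MYOZ2, a Z-disc protein, differed by -8.74 ± 0.57 on the log2 scale (SE, 3 arrays per tissue), and the mitochondrial creatine kinase CKMT2 by -8.64 ± 0.17, both lower in adipose tissue. Their adipose means lay under 6, at 4.70 and 3.39 in abdominal fat, so the size of these differences, and their order among muscle genes, rests on the background. Genes higher in adipose tissue included PCK2, mitochondrial phosphoenolpyruvate carboxykinase (5.45 ± 0.26), the cytochrome P450 CYP2B6 (5.36 ± 0.39), the fibrinogen chain FGG (4.86 ± 0.25) and leptin, LEP (4.75 ± 0.29), whose muscle means were also under 6, at 5.34, 5.11, 3.75 and 5.22. The adipocyte regulator PPARG was 4.24 ± 0.20 higher and adiponectin, ADIPOQ, 3.59 ± 0.25 higher. For each of these genes every adipose array lay on one side of every muscle array. The naming rule required this of genes taken for the size of their difference. Of the 24016 probe sets tested with limma, 12628 passed an adjusted p of 0.05, 6295 higher and 6333 lower in adipose tissue, which is 49.8% higher. With each array centred on its median, 14165 passed and 39.2% of them were higher, so the balance of directions rests on the scaling. By 1 probe set per gene with a symbol, 2926 genes were higher and 2699 lower. That probe set is the brightest over all arrays, most of them fat, so the rule can favour one brighter in fat, as for CKM.

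Contractile genes were lower in adipose tissue almost throughout. In the sarcomere list, 24 of 27 measured members were lower and 3 higher, with a median difference of -6.69 (camera adjusted p = 2.47e-10; adjusted p = 0.273 with an estimated correlation). MYOZ2, the small muscle protein SMPX (-8.52), myotilin, MYOT (-7.83), and the fast myosin heavy chain MYH1 (-7.79) were among the lower members, and skeletal actin, ACTA1, differed by -5.20 ± 0.61, with muscle values near the top of the scale (mean 13.84), so this size is not exact. The higher members were the tropomyosins TPM1 (2.09) and TPM3 (1.33), which many cell types express, and the slow myosin heavy chain MYH7 (0.60, adjusted p = 0.0343). The MYH7 value belongs to its brightest probe set and the call was lost with centred arrays (adjusted p = 0.0693), with array weights (0.053) and without muscle replicate 1 (0.0735), 2 (0.0519) or 3 (0.117), abdominal replicate 1 (0.0613) or 2 (0.0626), or subcutaneous replicate 2 (0.0538). Another MYH7 probe set differed by -7.16. In excitation-contraction coupling, 8 of 11 members were lower and 2 higher (median -4.47; camera adjusted p = 0.000215; adjusted p = 0.152 with an estimated correlation). They included sarcolipin, SLN (-7.84), the calcium pump ATP2A1 (-7.20), junctophilin JPH1 (-7.14) and STAC3 (-5.89). The calcium channel subunit CACNB1 (2.06) and ASPH (1.81), whose products include an aspartate hydroxylase found in many tissues, were higher. Of 8 myogenic regulators 7 were lower and none was higher, among them KLHL41 (-8.42), MYF6 (-6.58), MSTN, the growth inhibitor myostatin (-3.29), and MYOG (-2.67) (median -2.23; camera adjusted p = 0.00054; adjusted p = 0.132 with an estimated correlation). The MSTN means were under 6 in every tissue, at 5.38 in muscle, so the size of its difference is not exact. Muscle replicates 1, 2 and 3 read 4.71, 7.21 and 4.22 for MSTN. Outside these lists ANKRD1, a stress-responsive muscle protein, differed by -8.09 and the nicotinamide riboside kinase NMRK2 by -8.08. The counts of these lists were the same adjusted over the list alone.

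Oxidative phosphorylation and tricarboxylic acid cycle genes were lower in adipose tissue. Of 43 members of oxidative phosphorylation 41 were lower, with a median of -1.11 (camera adjusted p = 1.01e-11; adjusted p = 0.273 with an estimated correlation). The muscle isoforms COX6A2 (-5.53) and COX7A1 (-3.70) and ATP5MC1 (-2.56) were among the lower members, and the ubiquitous subunit COX8A was higher (1.86). In the tricarboxylic acid cycle 14 of 15 members were lower and none higher, IDH2 by the most at -3.53 (median -0.98; camera adjusted p = 1.36e-05; adjusted p = 0.219 with an estimated correlation). Glycolysis and glycogen genes had 15 lower and 3 higher of 21 (4 higher when adjusted over the list alone), with a median of -1.37 (camera adjusted p = 0.00054; adjusted p = 0.152 with an estimated correlation). Muscle glycogen phosphorylase, PYGM (-8.16), PGAM2 (-6.71) and ENO3 (-5.76) were lower, while the isoforms of wide expression PGAM1 (2.13), HK1 (1.76) and ENO1 (1.04) were higher. The proteasome had 23 of 25 subunits lower, by a median of -0.80, with PSMD14 (-1.30) and PSMC1 (-1.17) lowest (camera adjusted p = 3.93e-06; adjusted p = 0.31 with an estimated correlation). With the preset correlation 3 further lists did not pass the list test. Mitochondrial fatty acid oxidation had 9 lower, such as the fatty acid binding protein FABP3 (-7.33), UCP3 (-5.08) and CPT1B (-3.46), and 5 higher of 22 (10 and 6 adjusted over the list alone; camera adjusted p = 0.124). Creatine and phosphate metabolism had CKMT2 and 4 others lower and 3 higher, including the brain-type creatine kinase CKB at 3.41 (camera adjusted p = 0.212). Another of the higher members was CKM by its brightest probe set, while its other probe set differed by -7.64. With the mean of all probe sets of a gene the creatine list passed (adjusted p = 0.0349). Thermogenic genes had 4 lower of 7, PPARGC1A by -2.98, and 1 higher, the lipid droplet protein CIDEA at 2.87 (camera adjusted p = 0.104). Apart from glycolysis and fatty acid oxidation, counts were the same adjusted over the list alone. The uncoupling protein UCP1 itself differed by 0.13 ± 0.47 (adjusted p = 0.838). Its means were 3.86, 3.41 and 3.22 in abdominal fat, muscle and subcutaneous fat, all under 6, so no lack of a difference is read from it. Abdominal replicate 2 read 5.48, against 2.88 to 3.79 on the other arrays.

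Lipogenesis, adipocyte identity and lipid droplet genes were higher in adipose tissue. De novo lipogenesis had 15 higher and 2 lower of 19 (median 2.35; camera adjusted p = 0.000237; adjusted p = 0.455 with an estimated correlation), including ELOVL6 (4.64), THRSP (4.26), fatty acid synthase, FASN (3.38 ± 0.35), and stearoyl-CoA desaturase, SCD (3.10 ± 0.42), which lay near the top of the scale in fat (13.53 in subcutaneous fat), so that this size is not exact. ACACB, whose product limits fatty acid entry into mitochondria, was lower (-3.37), as was the desaturase FADS2 (-0.60). Adipocyte identity genes had 15 higher and 4 lower of 19 (median 1.78; camera adjusted p = 0.00119; adjusted p = 0.132 with an estimated correlation). Beside LEP, PPARG and ADIPOQ, the higher members included TRARG1 (4.37), the retinol carrier RBP4 (4.12), and hormone-sensitive lipase, LIPE (3.82). FABP4 was bright in every tissue, at 11.91 ± 0.66 (SD, n = 3) in muscle and 13.72 ± 0.06 in abdominal fat. In fat this probe set lay near the top of the scale, and on abdominal replicates 2 and 3 and subcutaneous replicate 2 it was the array maximum. It differed by 1.79, and the other FABP4 probe set by 3.52. Its lower members were the insulin-responsive glucose transporter SLC2A4 (-1.77), which muscle also uses, TMEM120A (-1.03), resistin, RETN (-0.73), and the transcription factor KLF15 (-0.39). Lipid droplet and lipolysis genes had 13 higher and 2 lower of 18 (median 2.04; camera adjusted p = 0.00158; adjusted p = 0.273 with an estimated correlation), with CIDEC (4.06) and G0S2 (3.40) among the higher. PLIN5 (-3.11), the perilipin of oxidative tissues, and PLIN3 (-0.51) were lower. In triacylglycerol synthesis 11 of 21 were higher, such as DGAT2 (3.56) and PCK1 (3.22), and 6 lower, and the list test did not pass (camera adjusted p = 0.162), but did among probe sets over 6 on at least 3 arrays (adjusted p = 0.0248). These counts were the same adjusted over the list alone.

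Blood vessel, matrix, macrophage and complement genes were also higher in adipose tissue. Endothelial markers had 14 higher and none lower of 16, with ROBO4 at 2.93 and PECAM1 at 2.87 (median 1.97; camera adjusted p = 3.93e-06; adjusted p = 0.152 with an estimated correlation). All 9 basement membrane genes were higher, among them COL4A1 (2.70) and NID1 (2.63) (median 2.03; camera adjusted p = 9.86e-05; adjusted p = 0.315 with an estimated correlation). Fibrillar collagen and matrix genes had 24 higher and 1 lower of 32 (median 1.41; camera adjusted p = 9.9e-05; adjusted p = 0.455 with an estimated correlation). TIMP3 (2.72), ELN (2.48) and SPARC (2.33) were among the higher and the collagen chain COL6A2 was lower (-0.63). Pericyte and smooth muscle markers had 8 higher, MCAM by 3.48, and 1 lower of 12 (9 higher adjusted over the list alone; median 1.19; camera adjusted p = 0.0424; adjusted p = 0.455 with an estimated correlation). The lower member was smoothelin, SMTN (-1.83), a contractile smooth muscle protein. This call was lost without muscle replicate 1 (adjusted p = 0.0783) or 3 (0.055), without abdominal replicate 1 (0.0531) or 2 (0.0532), and among probe sets over 6 on at least 3 arrays (0.0996). Macrophage markers had 16 of 17 higher, such as CD68 (3.38), CD14 (2.83) and C1QC (2.61) (median 2.20; camera adjusted p = 0.000125; adjusted p = 0.455 with an estimated correlation). Complement and acute phase genes had 18 of 19 higher, including CFB (3.67) and C4A (3.20) (median 2.27; camera adjusted p = 5.91e-06; adjusted p = 0.132 with an estimated correlation). Interferon and antigen presentation genes had 12 higher, MX1 by 2.28, and 1 lower of 17, the chemokine CXCL10 (-1.30) (median 0.96; camera adjusted p = 0.0248; adjusted p = 0.455 with an estimated correlation). That list was lost without muscle replicate 3 (adjusted p = 0.0641). Preadipocyte and growth factor genes had 17 higher and none lower of 29, with SFRP2 at 3.14 (median 0.85; camera adjusted p = 0.0022; adjusted p = 0.448 with an estimated correlation). Except for the pericyte list, counts were the same adjusted over the list alone.

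In all, 18 of the 34 lists passed, 11 higher and 7 lower in adipose tissue, with a preset correlation of 0.01. With an estimated correlation camera passed 0, and 9 had an unadjusted p under 0.05; fry passed 29. The 3'/5' ratios above moved with the same contrast as every one of these groups. Of the 146 genes that the naming rule took, 144 passed and MSLN and UCP1 did not. CKM, muscle creatine kinase, was 1.46 higher by its brightest probe set and lower by its other probe set (-7.64, adjusted p = 4.23e-08). Each p-value measures the spread between these samples, because the labels do not tie samples to separate animals.

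**Figure D2:**
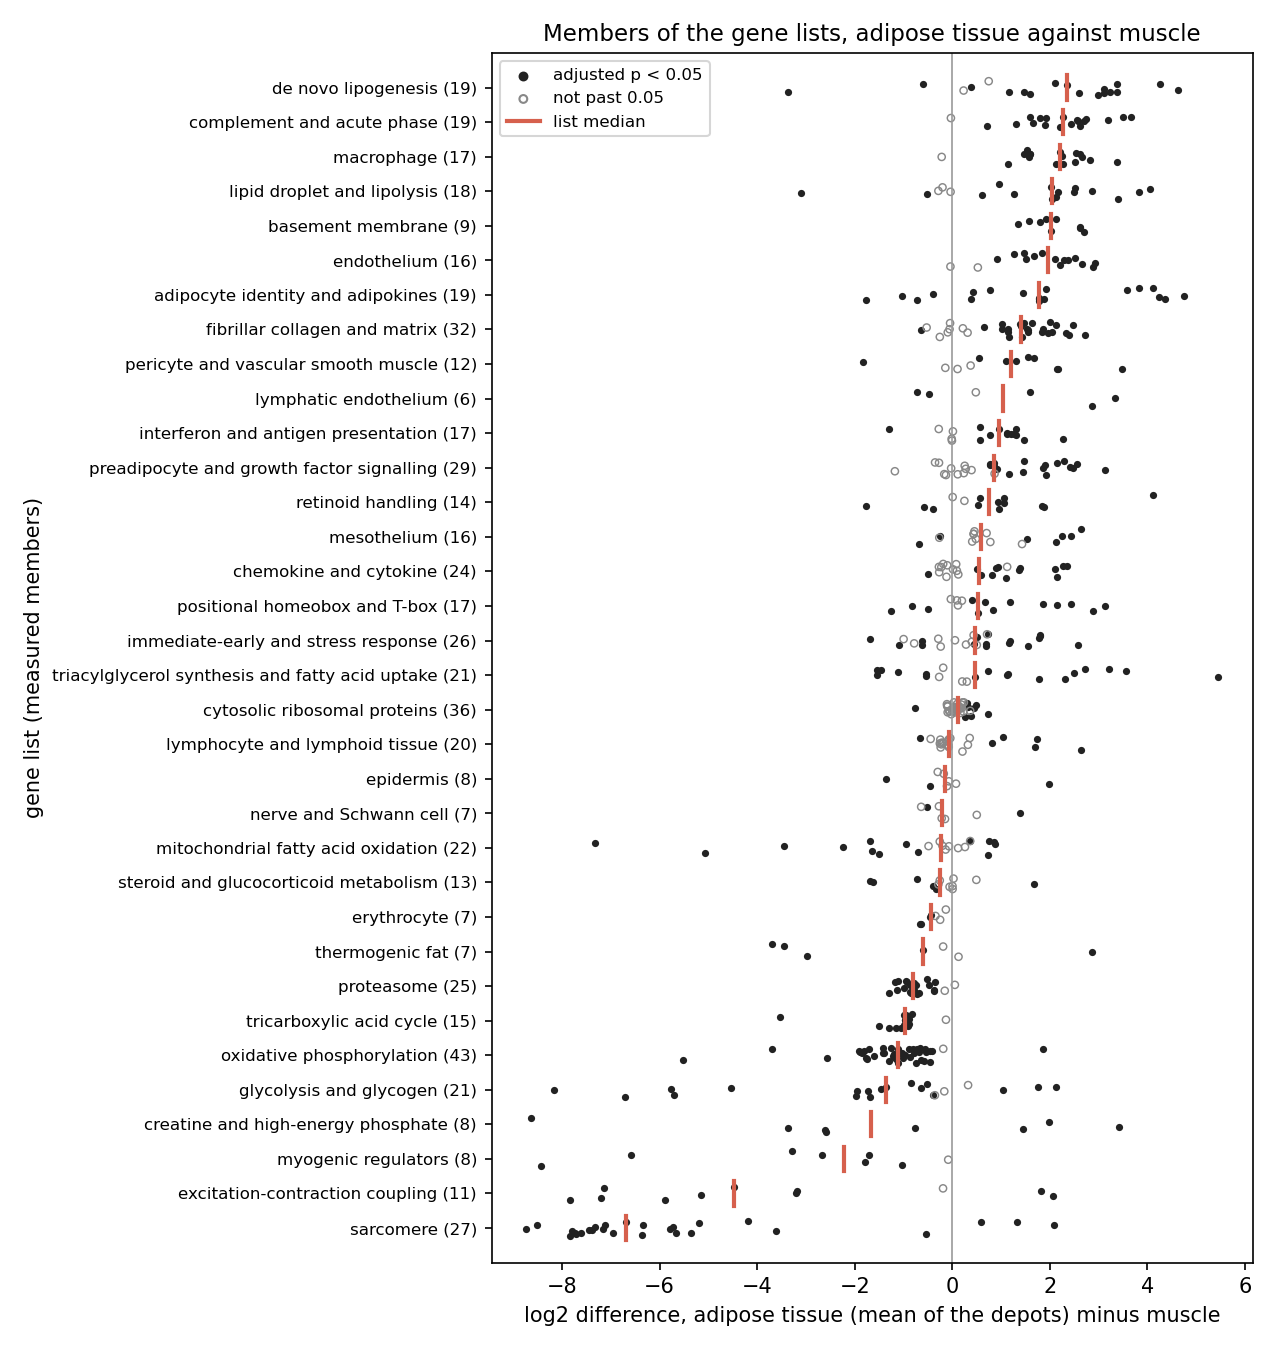
Log2 difference, adipose tissue minus muscle, of each measured member of the 34 lists, ordered by list median. Filled points passed an adjusted p of 0.05 over all probe sets, open points did not, and the bar is the list median, from -6.69 for the sarcomere to 2.35 for de novo lipogenesis.

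Each depot was also compared with muscle by itself. PCK2 reached 10.61 ± 0.23 (SD, n = 3) in abdominal and 10.97 ± 0.35 in subcutaneous fat against 5.34 ± 0.65 in muscle. MYOZ2 stood at 4.70 and 4.62 in the depots and at 13.39 in muscle. PCK1, the cytosolic enzyme of glyceroneogenesis, was at 11.19 in abdominal fat, 8.79 in subcutaneous fat and 6.77 in muscle, and the difference between the depots did not pass (2.39, adjusted p = 0.109). In the limma fit, abdominal fat differed from muscle at 11196 probe sets, 5650 higher and 5546 lower. Subcutaneous fat differed at 11299, 5913 higher and 5386 lower. Those higher were 50.5% and 52.3% of the calls as deposited, and 40.1% and 41.2% with arrays centred on their medians.

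The last comparison asked how the abdominal depot differed from the subcutaneous depot. The chemokine CXCL14 had the largest difference, -4.19 ± 0.50 (SE, 3 arrays per depot; adjusted p = 0.00849), with a mean of 6.55 in abdominal and 10.75 in subcutaneous fat. Subcutaneous fat was also higher for the homeobox gene IRX3 (-2.31 ± 0.17, adjusted p = 0.00136), the endothelial adhesion molecule E-selectin, SELE (-2.28 ± 0.23, adjusted p = 0.00426), and the sulfate transporter SLC13A4 (-1.94 ± 0.24, adjusted p = 0.00955). SLC13A4 was dim, with means of 3.62 and 5.55 in the depots, and its other probe sets differed by -0.53 (adjusted p = 0.369) and -0.125 (0.818). Abdominal fat was higher for the small heat shock protein HSPB3 (2.997 ± 0.41, adjusted p = 0.0164), the cytokine IL6 (2.97 ± 0.37, adjusted p = 0.00955), the acyl-CoA synthetase ACSM2B (2.41 ± 0.31, adjusted p = 0.0105) and the fatty acid elongase ELOVL7 (2.16 ± 0.18, adjusted p = 0.00168). Abdominal and subcutaneous arrays did not overlap for any of these genes, which the rule that named them required. ACSM2B was dim as well, with means of 5.70 and 3.29 in abdominal and subcutaneous fat. The lower depot's mean was under 6 for IL6 (4.16), HSPB3 (4.94), ELOVL7 (5.41) and SELE (4.22). These depot genes, from CXCL14 to ELOVL7, are the 8 of 27 passing named genes whose call held with each array left out in turn. Of these, IL6 did not pass with the leading title number as a block. SPP2, a secreted bone matrix protein (-2.16, adjusted p = 0.0141), was lost only without abdominal replicate 3 (0.0564).

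The other 18 lost their call without at least 4 of the arrays. The enzymes of glycerolipid synthesis GPAT3 (3.45 ± 0.62, adjusted p = 0.0349) and GK (1.34, adjusted p = 0.0263) reached up to 0.112 and 0.0861 with an array left out. The GK means were 5.999 in abdominal and 4.66 in subcutaneous fat, both under 6. The Wnt modulator SFRP2 (2.45, adjusted p = 0.0248) reached 0.0867, the imprinted gene NNAT (2.42, adjusted p = 0.0293) 0.0942, and the growth factor FGF2 (1.33, adjusted p = 0.0232) 0.0854. For the endothelial genes TEK (1.09, adjusted p = 0.0293) and PLVAP (0.97, adjusted p = 0.0293) the highest values were 0.0925 and 0.0969. CYP2B6 (-2.68, adjusted p = 0.0293) reached 0.0932 and CRABP2, a retinoic acid binding protein (-1.30, adjusted p = 0.0354), 0.111. Named calls lost numbered 12, 4 and 3 without muscle replicates 1, 2 and 3, with adjusted p up to 0.0704, 0.055 and 0.0542. They numbered 13, 17 and 18 without abdominal replicates 1, 2 and 3 (up to 0.153, 0.137 and 0.144), and 17, 12 and 16 without subcutaneous replicates 1, 2 and 3 (up to 0.131, 0.115 and 0.138). Among genes fixed in advance, LEP differed by 0.31 ± 0.34 (adjusted p = 0.771), ADIPOQ by 0.79 ± 0.29 (0.239), PPARG by 0.47 ± 0.23 (0.402), FABP4 by 0.04 ± 0.27 (0.974) near the top of the scale and by 0.43 (0.623) with its other probe set, FASN by -0.19 ± 0.40 (0.907), SCD by -0.32 ± 0.49 (0.853), again near the top of the scale, and HOXA5 by 0.24 ± 0.18 (0.635).

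**Figure D3:**
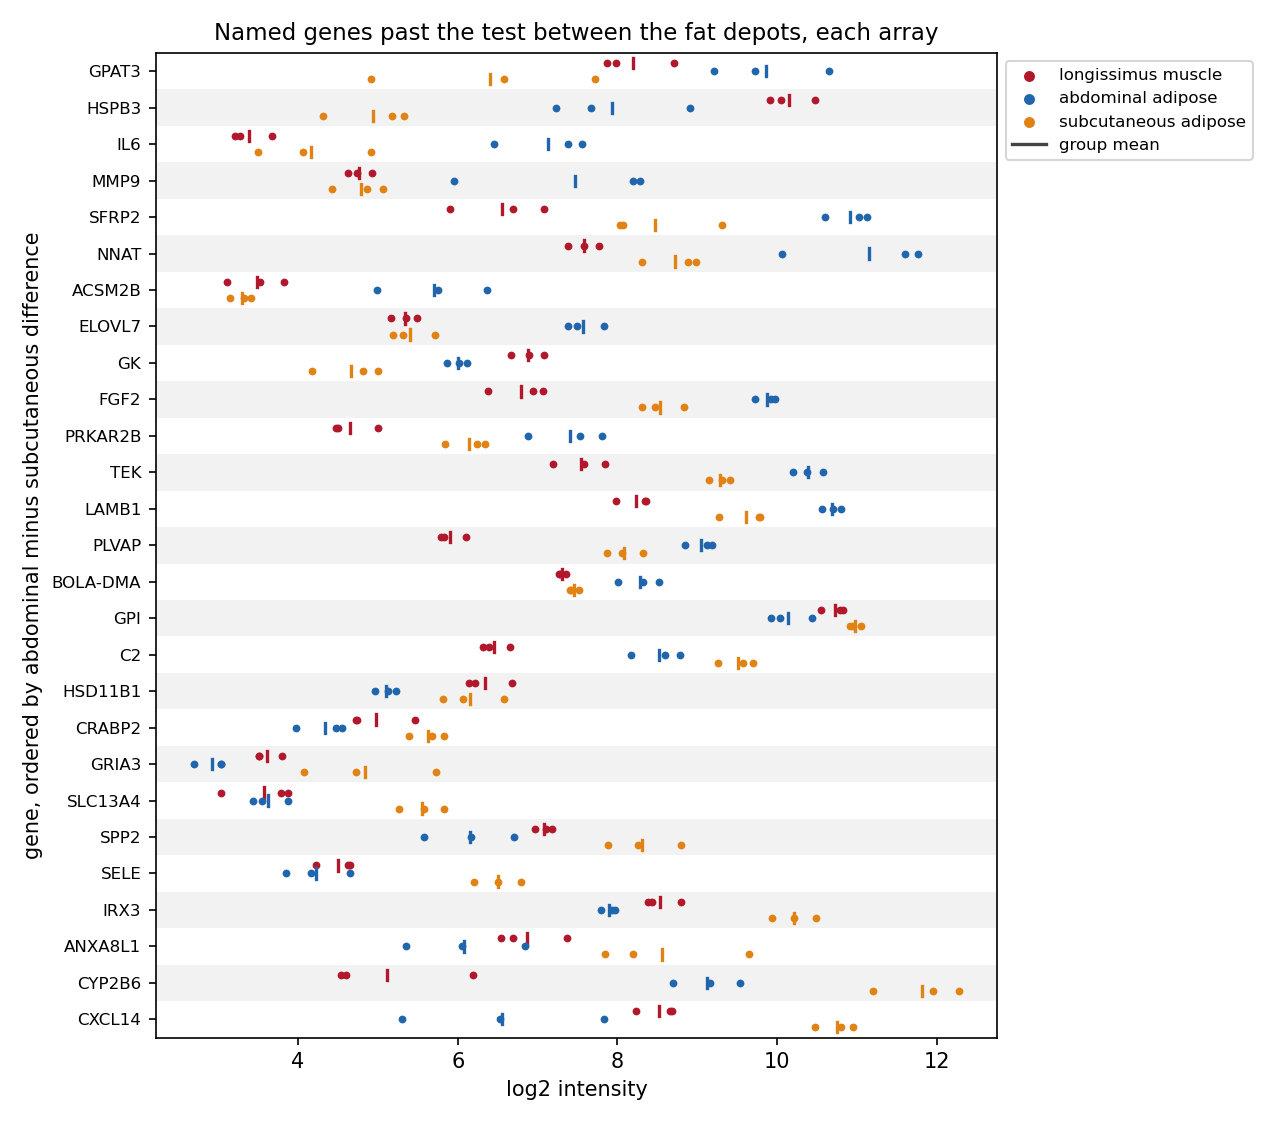
Log2 intensity of the 27 named genes that passed between the fat depots, one point per array and a bar at each group mean, with muscle shown beside them. Genes are ordered by the abdominal minus subcutaneous difference, from 3.45 for GPAT3 to -4.19 for CXCL14.

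Several lists moved between the depots although few of their members passed alone. Endothelial markers were higher in abdominal fat by a median of 0.55, with 2 of 16 members passing over all probe sets and 6 when adjusted over the list alone (camera adjusted p = 2.39e-07; adjusted p = 0.132 with an estimated correlation). Immediate-early and stress response genes were higher by a median of 0.54, with 0 of 26 passing over all probe sets and 7 adjusted over the list alone, CCN1 at 0.96 having the smallest p (camera adjusted p = 4.89e-07; adjusted p = 0.219 with an estimated correlation). Proteasome subunits were lower by a median of -0.34, with 0 of 25 passing and 9 lower adjusted over the list alone, PSMA5 at -0.56 (camera adjusted p = 1.44e-06; adjusted p = 0.31 with an estimated correlation). Pericyte genes (median 0.50, 0 of 12 and 2 adjusted over the list alone) and interferon genes (median 0.29, 1 of 17 in both counts, BOLA-DMA at 0.83) were higher, with camera adjusted p of 0.00166 and 0.00203 (adjusted p = 0.315 and adjusted p = 0.347 with an estimated correlation). These 5 lists kept their call with each array left out, while the BOLA-DMA call was lost without 6 of the arrays (adjusted p up to 0.0959). With an estimated correlation camera passed 0 of the 34 lists between the depots, and 3 had an unadjusted p under 0.05. Fry passed 6, of which endothelium, immediate-early genes, proteasome and adipocyte identity are among the 9 that camera passed, and not pericytes (adjusted p = 0.0808), interferon (0.084), oxidative phosphorylation (0.125), chemokines (0.28) or fatty acid oxidation (0.302).

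The other 4 list calls each ended without at least 1 array. Oxidative phosphorylation was lower by a median of -0.16, with 0 of 43 passing and 1 lower adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.63 with an estimated correlation), and was lost without abdominal replicate 1 (0.077). Adipocyte identity was higher by a median of 0.13 with 0 of 19 passing in either count (camera adjusted p = 0.0248; adjusted p = 0.219 with an estimated correlation). It was lost without abdominal replicates 1 (0.0585) or 2 (0.0532) or subcutaneous replicate 2 (0.0887). Chemokines had a median of 0.10, with IL6 higher and CXCL14 lower, and 6 higher and 2 lower of 24 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.476 with an estimated correlation). Fatty acid oxidation had a median of 0.06, with 0 of 22 passing and 1 higher adjusted over the list alone (camera adjusted p = 0.0424; adjusted p = 0.572 with an estimated correlation). The chemokine list was lost without muscle replicate 3 (0.0564), abdominal replicates 1 (0.11) or 3 (0.0806) or subcutaneous replicate 1 (0.163). Fatty acid oxidation was lost without muscle replicates 2 (0.0514) or 3 (0.0641), abdominal replicate 1 (0.077) or subcutaneous replicate 3 (0.105).

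Mesothelial markers, which would come from the lining of the abdominal cavity, did not pass as a list (median 0.11; camera adjusted p = 0.105). Over all probe sets 1 of 16 passed, ANXA8L1 at -2.48 (adjusted p = 0.0457), and adjusted over the list alone 5 were higher and 1 lower. The ANXA8L1 call was lost with each of the 9 arrays left out in turn (up to 0.136). MSLN, mesothelin, stood at 6.32, 4.39 and 6.41 on abdominal replicates 1, 2 and 3 and between 3.97 and 4.20 in subcutaneous fat (difference 1.64, adjusted p = 0.122). Without abdominal replicate 2 the MSLN adjusted p was 0.00471 and that of the list 1.55e-06, and without subcutaneous replicate 1 the list reached 0.0473. Positional homeobox genes had IRX3 lower in abdominal fat and, adjusted over the list alone, 1 higher and 6 lower of 17, with a median of 0.05, a mean of -0.19 and a test direction of lower (camera adjusted p = 0.287). Preadipocyte genes had SFRP2 and FGF2 higher and, adjusted over the list alone, 3 higher and 4 lower of 29, with a median of -0.09, a mean of 0.07 and a test direction of higher (camera adjusted p = 0.482). Fibrillar collagen genes had none passing, and 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.314). LOX, the collagen cross-linking enzyme, differed by -1.69 (adjusted p = 0.054).

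In the limma fit, 314 probe sets passed between the depots, 154 higher and 160 lower in abdominal fat, and 3473 had an unadjusted p under 0.05. With array weights 1034 passed. The count was 132, 352 and 491 without muscle replicates 1, 2 and 3, 105, 74 and 57 without abdominal replicates 1, 2 and 3, and 67, 90 and 79 without subcutaneous replicates 1, 2 and 3. With the leading title number as a block 118 passed, 81 of them among the 314, and 14 of the 27 named calls did not pass.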

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

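The tests on the mesothelial genes and the share of calls kept with centred arrays were chosen only after the result was seen. The other tests were set beforehand.

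At 314 probe sets the difference from muscle itself differed between the fat depots, which is the abdominal against subcutaneous test. At 12 of these the depots passed on opposite sides of muscle, 4 of them with abdominal fat higher. CXCL14 was lower than muscle in abdominal fat (-1.97) and higher in subcutaneous fat (2.22), a difference of -4.19. GPAT3 was higher in abdominal (1.67, adjusted p = 0.0495) and lower in subcutaneous fat (-1.78, adjusted p = 0.0382), a difference of 3.455, so it passed against muscle only narrowly. IRX3 stood at -0.64 and 1.68, a difference of -2.31. SPP2 stood at -0.94 and 1.23, a difference of -2.16. The transglutaminase TGM2, chosen after its values were seen, stood at 1.23 and -0.76, a difference of 1.99. MAB21L1, chosen in the same way, stood at -0.89 and 0.89, a difference of -1.78, with means of 2.96, 3.85 and 4.74 in abdominal fat, muscle and subcutaneous fat, all under 6. By its second probe set the pyruvate dehydrogenase kinase PDK4 stood at 0.62 (adjusted p = 0.0371) and -0.79 (0.0126), a difference of 1.415. Its brightest probe set (0.91, adjusted p = 0.0715) and another (1.099, adjusted p = 0.173) did not pass between the depots. CRABP2 stood at -0.64 (adjusted p = 0.0467) and 0.66 (0.0426), a difference of -1.30, with means of 4.33, 4.98 and 5.63, also all under 6. The depot calls of GPAT3 and CRABP2 were each lost without 6 of the arrays. For CXCL14, IRX3, SPP2, TGM2 and MAB21L1 both adjusted p against muscle were 0.0233 or lower.

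Other splits of the arrays were refitted with 2 groups. For adipose tissue against muscle, 1 of 84 splits, the real one, gave as many probe sets, a share under the bound of 0.05. The real split gave 12133 and the highest other gave 13, which argues against chance but does not exclude it. Every other split puts muscle and fat arrays in the same group, which widens the spread there. The splits also treat arrays as exchangeable, although arrays with the same title number deviated together. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 10234 for abdominal fat against muscle, 10073 for subcutaneous fat against muscle and 358 between the depots, 1 split in each case, and the highest other gave 0 in each.

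Of the 24016 probe sets 12628 differed between adipose tissue and muscle, and the direction of those calls went with brightness. A higher background on the muscle arrays is argued against as the source of most calls, since 29.89% of the calls were dim and 69.73% of the bright probe sets were called. Dim calls were lower in adipose tissue in 72.92% of cases, against 40.44% of bright calls, and the part they make up cannot be told apart from a background difference, as background and tissue change together. A median shift left by the normalization is argued against as the source of the calls, since centring kept 94.1% of them, although the test set beforehand was undecided (their number changed by a factor of 1.122, over its bound), while the balance of directions moved from 49.8% to 39.2% higher. A biological difference between the tissues in how many genes are transcribed may add to the pattern and was not tested.

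Mesothelial genes were lower on abdominal replicate 2 than on abdominal replicates 1 and 3. UPK1B read 7.90, 3.77 and 7.38, CLDN1 8.26, 5.41 and 7.97 and the brightest member that separated them, C3, 12.48, 10.64 and 11.94, while EFEMP1, which all 3 tissues hold at over 8.9, read 11.39, 11.71 and 11.80. A shift of the array at the expression level of these genes is argued against. Random lists matched on expression reached a median of at most 0.1256 for the lower of replicates 1 and 3 minus replicate 2. The normalization had left near-equal array medians, so only a shift tied to expression level was open to this test. Genes of the random lists need not vary together, as markers of a cell type may, so the lists give no p-value. The lower of replicates 1 and 3 exceeded replicate 2 for 13 of 16 members, against 28.4% of all genes. The 13 include KRT7 and KRT8, by only 0.086 and 0.044 near background, and ANXA8L1, which was brightest in subcutaneous fat. CLDN15, EFEMP1 and BCHE went the other way. The median over the 16 of the lower of replicates 1 and 3 minus replicate 2 was 0.76, at percentile 100 of those random lists. That is consistent with a different share of mesothelial cells among the abdominal samples, through dissection or anatomy, as a hypothesis found on the same data; the labels name no site within the abdomen, C3 is also in the complement list and PDPN in the lymphatic list.

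Arrays whose titles begin with the same number deviated together from their tissue means. Between numbers 4 and 5, 45 probe sets differed by at least 1 in the same direction in all 3 tissues, against 8 in the largest class with 1 tissue apart, a ratio of 5.62. With a minimum difference of 0.5 these counts were 238 and 127, a weaker excess, and with 1.5 they were 12 and 0. The major histocompatibility gene BOLA-DQA5, chosen after its values were seen, read 3.73, 3.27 and 3.40 on the number 4 arrays of muscle, abdominal and subcutaneous fat and 6.77, 7.94 and 7.53 on the number 5 arrays. This would go with the same animal behind each number, which the labels do not state. The labels count 9 bulls for the 9 arrays, which goes against a shared animal. The 9 hybridisation control probe sets did not correlate throughout between arrays of the same number (lowest -0.843), but they do not test RNA extraction or labelling and no label gives a batch or a day, so a shared batch or day cannot be told apart from the same animal.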

How the results depend on the processing

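The count with 1 probe set per gene was chosen after seeing the data. For adipose tissue against muscle, the count of 12628 became 8350 among the 12008 probe sets with the highest mean, 5376 with a log2 difference of 1 or more and 5756 with 1 probe set per gene. A log2 difference of 1 or more and 1 probe set per gene gave 5346 and 5285 for abdominal fat and 5472 and 5318 for subcutaneous fat against muscle. These settings test or admit fewer probe sets by construction, as do 36 at an adjusted p under 0.01, 178 with a log2 difference of 1 or more and 167 with 1 probe set per gene between the depots, against 314. Array weights gave 1034 there, and leaving out an array 57 to 491: 132, 352 and 491 without muscle replicates 1, 2 and 3, 105, 74 and 57 without abdominal replicates 1, 2 and 3, and 67, 90 and 79 without subcutaneous replicates 1, 2 and 3. The cause was not tested. Lists past the threshold went from 18 to 0 with an estimated correlation and 29 with fry for adipose tissue against muscle, and from 9 to 0 with an estimated correlation between the depots (6 to 11 with an array left out). No call of a named gene or list reversed in the alternatives run. For a named gene these kept the same probe set, so the choice of probe set was not varied. Against muscle, probe sets of CKM, MYH7, EGR1, LAMC1 and RPL3 passed in opposite directions. Of the named genes, 135 of 144 calls against muscle and 7 of 27 between the depots held in every alternative, and 0 of the list calls did. With the leading title number as a replicate block, with 3 residual degrees of freedom in place of 6, 118 probe sets passed between the depots, 81 of them among the 314, and 14 of the 27 named depot calls did not pass; IL6 had an adjusted p of 0.0526, the chemokine and fatty acid oxidation lists 0.198 and 0.143, the triacylglycerol list 0.0122 and the sarcomere list 8.91e-05. By the labels the samples share only a number. Deviations of same-numbered arrays correlated at 0.13 and 0.18 (muscle and abdominal), 0.04, 0.15 and 0.09 (muscle and subcutaneous) and 0.33 and 0.36 (abdominal and subcutaneous). Different numbers lay between -0.32 and 0.09 for abdominal and subcutaneous arrays and reached 0.17 (muscle replicate 3 and abdominal replicate 3), and subcutaneous replicate 1 correlated more with muscle replicate 3 (0.08) than with muscle replicate 1 of its own number. Signal over background limits the dim probe sets: 11318 of 24016 had a log2 value over 6 on fewer than 3 arrays, and the median absolute difference was 0.57 for dim calls and 1.07 for bright calls.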

Other observations

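All tests reported in this part were set beforehand, and examples outside the naming rule were chosen after their values were seen.

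Between adipose tissue and muscle, 12 more lists did not pass the list test. Members of each passed, but so did 5625 of all 9155 genes, so passing members alone do not set a list apart. Positional homeobox genes had 10 higher and 3 lower of 17, with NR2F1 (3.13), MEIS2 (2.89) and HOXA9 (2.44) higher (camera adjusted p = 0.0563). Retinoid handling genes had 9 higher and 3 lower of 14, from RBP4 (4.12) to CRABP1 (-1.77), a cellular retinoic acid binding protein (camera adjusted p = 0.099). Immediate-early genes had 12 higher, such as KLF4 (1.80) and EGR1 (2.58 by its brightest probe set, -0.57 by its other, dim one, adjusted p = 0.00589), and 4 lower of 26, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.104), and mesothelial genes had 5 higher and 2 lower of 16, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.104). Without abdominal replicate 2 the mesothelial list reached 0.00515, and without subcutaneous replicate 1 the immediate-early list reached 0.0497. Among probe sets over 6 on at least 3 arrays the retinoid list reached 0.0148 and the mesothelial list 0.0457. The homeobox list reached 0.0457 with the mean of all probe sets of a gene, 0.0391 without muscle replicate 3, 0.0435 without abdominal replicate 2 and 0.0468 without subcutaneous replicate 2. Chemokines had 12 higher, such as CXCL5 (2.36) and CCL2 (2.10), and 1 lower of 24, CCL20 (-0.49), or 13 and 1 adjusted over the list alone (camera adjusted p = 0.151). Steroid metabolism had HSD17B4 higher (1.68) and 5 lower of 13, HSD17B8 at -1.70 (camera adjusted p = 0.317).

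Markers of other cell types in the same comparison were mixed. Erythrocyte genes had 4 lower of 7 and none higher (camera adjusted p = 0.162). Each of these calls was lost with an array left out: AHSP without muscle replicates 2 or 3, abdominal replicate 2 or subcutaneous replicate 1 (up to 0.103), ALAS2 without muscle replicates 1 or 2 (up to 0.0905), EPB42 without muscle replicate 2 (0.0787) and HBB without muscle replicate 1, abdominal replicates 1 or 3 or subcutaneous replicates 1 or 3 (up to 0.172). The means of AHSP and ALAS2 were under 6 in every tissue, and those of HBB in both depots. Lymphocyte genes had 5 higher, IGHM at 1.74, and 1 lower of 20 (camera adjusted p = 0.77; CXCL13 lost without muscle replicates 2, 0.0814, or 3, 0.08), and lymphatic genes 3 higher, LYVE1 at 3.34, and 2 lower of 6, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.553). The lymphocyte list had a median of -0.07, a mean of 0.30 and a test direction of higher. Nerve genes had MBP higher (1.40) and ERBB3 lower (-0.52) of 7, with a median of -0.22, a mean of 0.01 and a test direction of lower (camera adjusted p = 0.654). Epidermal genes had KRT5 higher (1.99) and 2 lower of 8, or 1 and 1 adjusted over the list alone, with KRT15 lost without muscle replicates 1 or 2, abdominal replicates 1 or 3 or subcutaneous replicates 1 or 2 (up to 0.176) (camera adjusted p = 0.671). Cytosolic ribosomal proteins had 7 higher and 1 lower of 36, or 4 and 1 adjusted over the list alone, with a median of 0.11 that became -0.01 with centred arrays (camera adjusted p = 0.258).

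Between the depots, 9 further lists had at most 1 passing member. Glycolysis had GPI lower (-0.84; 4 lower of 21 adjusted over the list alone; camera adjusted p = 0.0897). Triacylglycerol synthesis had GK higher (3 higher of 21 adjusted over the list alone; camera adjusted p = 0.0563; 0.0347 without abdominal replicate 3 and 0.0135 without subcutaneous replicate 1). Complement had C2 lower (-0.998; 1 higher and 2 lower of 19 adjusted over the list alone; 0.72). Retinoid handling had CRABP2 lower (0.168), steroid metabolism HSD11B1 lower (-1.05; 0.482), basement membrane LAMB1 higher (1.08; 0.208) and lipid droplets PRKAR2B higher (1.27; 0.851), each with 1 passing adjusted over the list alone. Each of these passing members, from GPI to PRKAR2B, lost its call without at least 4 of the arrays. HSD11B1 (adjusted p = 0.0498) lost it with each of the 9 arrays left out in turn (up to 0.153), and its abdominal mean was 5.11. Creatine metabolism had none passing over all probe sets and 1 higher and 2 lower of 8 adjusted over the list alone (0.839), and erythrocyte genes none and 1 higher, HBB at 1.102 (0.181). No member passed in either count in the lists for de novo lipogenesis (0.453), sarcomere (0.353), excitation-contraction coupling (0.613), myogenic regulators (0.85), the tricarboxylic acid cycle (0.654), thermogenic fat (0.654), macrophages (0.445), lymphocytes (0.168), lymphatic vessels (0.839), nerve (0.427), epidermis (0.654) and ribosomal proteins (0.162). With an array left out, the sarcomere list reached 3.5e-05 (without abdominal replicate 3), macrophages 0.0146 (without abdominal replicate 1), collagens 0.0482 (without abdominal replicate 3), and lymphocytes 0.0212 and ribosomal proteins 0.0483 (without subcutaneous replicate 3). Median, mean and test differed in sign for the creatine (-0.16, -0.03, higher), lipid droplet (-0.005, -0.02, higher; a median of 0.004 with centred arrays), sarcomere (-0.05, 0.04, higher), tricarboxylic acid cycle (-0.02, 0.02, higher) and myogenic lists (0.01, -0.02, higher).

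Of the 314 depot calls, 128 had no symbol or several. The largest difference among these was -3.405 (adjusted p = 0.00426). DLK1, a preadipocyte regulator singled out after its values were seen, differed by 3.97 between the depots without passing (adjusted p = 0.123). Of 1242 genes with at least 2 called probe sets against muscle, 194 had calls in both directions. On abdominal replicate 3 the BioB hybridisation control read 174.6 against 57.8 to 113.5 on the other arrays, 2.5 times their median, while BioC, BioDn and CreX lay at 1.04, 1.01 and 1.04 times.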
